A study of Mus musculus with 12 samples.

How the data were processed

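Single-cell suspensions of mouse pituitaries were profiled with 10X Genomics single-cell RNA sequencing. Per the labels, the mice were of an FVB.129P2 strain, were acclimated for 1 week from 12 weeks of age, and were fed a diet with 60 kcal% fat or a control diet with 10% fat for 10 or 15 weeks. Each of the 12 samples pooled 2 to 3 pituitaries, with 10000 cells targeted. The labels give 4 samples at 10 weeks, 1 for each sex and diet, and 8 at 15 weeks, 2 for each. The sample titled as male on the high fat diet at 10 weeks carries the treatment value of the control diet in its characteristics, so its diet is stated in 2 ways. This did not enter any value here, because no cell was assigned to a sample.

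The deposited files hold raw UMI counts per gene and barcode in 1 matrix per time on the diet, and their values are whole numbers. The submitters' processing notes name Cell Ranger 3.1.0, STAR, Seurat and the mm10 genome. The read end captured by the kit, the strand use of the counting and any step between the 12 samples and the 2 matrices are not given in the sources used here. All barcodes of both matrices carried 1 suffix and the matrices shared 0 barcodes. Each matrix was treated as 1 pooled sample, and the tests of diet and sex planned for a map from cells to samples were not made. With 1 sample per time, no p-value, standard error or count of changed genes was computed.

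Cells were kept with at least 200 genes and under 25% mitochondrial UMIs. This left 2216 of 2676 barcodes at 10 weeks, where 440 had too few genes and 24 too many mitochondrial UMIs, and all 875 at 15 weeks. Kept cells had a median of 6193.5 UMIs and 1957.5 genes at 10 weeks and 1093 UMIs and 627 genes at 15 weeks. Scrublet, run within scanpy, marked 10 cells at 10 weeks (0.451%) and 2 at 15 weeks (0.229%). They were kept, and leaving them out was an alternative.

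Each matrix was clustered alone with scanpy 1.11.5 in Python 3.11.15: counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen after leaving out the genes of the fixed lists, the markers were added, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 followed. Clusters were named from 17 marker lists fixed before the data were examined. A cluster's score for a list was the mean log2 ratio of marker CPM, with 20 added, against the 25th percentile of the clusters. A name needed a score of at least 1 and at least 3 markers detected in 5% of cells at 2 times that base, and a cluster with a median UMI count under 1/3 of that of its matrix and no marker of the name among its top 10 genes stayed unnamed. A cluster whose leading genes held more markers of another list also stayed unnamed. The base was set after the data were examined, because a comparison with all other cells is dominated by lactotrope-like cells in these matrices. The rule left 2 clusters at 10 weeks (339 cells) and 0 at 15 weeks without a name. Lactotrope-like cells came from clusters 1, 2 and 4 at 10 weeks and 1, 2, 5 and 6 at 15 weeks, somatotrope-like cells from cluster 0 in each, and stem cell-like cells from clusters 3 and 5 at 10 weeks and 4 at 15 weeks.

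UMIs were summed per class and matrix and divided by the class total to give CPM. Shares have exact 95% binomial (Clopper-Pearson) intervals, and ratios of CPM have exact 95% intervals from the binomial split of the 2 Poisson sums. Both cover counting error only. Where a sum was 0, the ratio was taken against a floor of 3 counts. Genes with at least 20 UMIs in the class in at least 1 of the sums compared were considered, which gave 10441 genes in lactotrope-like, 6937 in somatotrope-like and 8615 in stem cell-like cells for the comparison of weeks. Medians of log2 ratios were computed with 0.5 added to each count.

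Of the 14 gene lists fixed before the data were examined, 12 were used for contrasts, and the pituitary hormone genes and the sex-linked transcripts were reported as levels. For each list, the median log2 CPM ratio of the measured members was set against 10000 random lists of the same size drawn from the 100 genes nearest in mean abundance. The relative value is the list's median minus the median of the random lists, its interval comes from 500 Poisson draws of the counts, and the percentile describes these 2 matrices only. The plan had only the list level as CPM. The matched lists were introduced after the data were examined, because the ratio between classes and matrices varied with abundance. For single genes the plan had the CPM ratio. After the data were examined, the value was taken relative to the median of all genes considered, since that median lay at 0.69, 0.22 and -0.06 in lactotrope-like, somatotrope-like and stem cell-like cells between weeks, and was moved to -0.28, -0.47 and -0.46 by leaving hormone, ribosomal and mitochondrial genes out of the total and to -0.25, -0.41 and -0.36 by TMM factors. Between classes it lay at 0.46 for somatotrope-like and 0.78 for stem cell-like against lactotrope-like cells at 10 weeks, and at 0.08 and -0.02 at 15 weeks. A scaling by 1 factor cannot change a value relative to this median, so such values are not tested by the scaling alternatives.

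Genes were named by a rule set before the data were examined. In each class compared between weeks, a gene was named as higher or lower where the whole interval of its CPM ratio lay beyond 1.5-fold. The 10 with the largest ratio in each direction were named, leaving out hormone genes, markers of other classes and ribosomal genes. The rule's condition on leaving out barcode suffixes could not apply with 1 suffix. The 4 members of each list with most UMIs in the class were also open to naming, in the comparison of weeks and between classes. Between classes, single genes were named from 5 of the lists only (oxidative stress defence, unfolded protein response and ER chaperones, inflammation, immediate early and heat shock genes, and metabolic hormone receptors), a choice made after the data were examined.

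Gene positions, exon lengths and overlaps on the other strand came from GENCODE M21 on GRCm38, the assembly also called mm10. The exon length of a gene was that of all its annotated exons merged. Of the 31053 genes in the table, 31011 (99.9%) matched it by gene identifier.

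The calculations were tested on simulated data drawn as Poisson counts from the mean profile and the real depths of each comparison of weeks, with 200 genes changed. Over 11282 genes in lactotrope-like cells, the size rule recovered 54% of the genes changed 2-fold and 99% of those changed 4-fold, over 7593 genes in somatotrope-like cells 44% and 97%, and over 8884 genes in stem cell-like cells 35% and 98%. The changed genes and the genes of both simulated lists were drawn only from genes with at least 20 expected UMIs at the depth of the shallower matrix. Genes scarcer than this were also considered by the size rule, and its recovery of them was not tested. The interval held the true value for 96.7%, 97.2% and 97.2% of unchanged genes. A list of 27 genes lowered by 2 on the log2 scale came out at -2.02, -2.23 and -1.97, and an unchanged list at 0.02, -0.10 and -0.08. For the somatotrope-like comparison the interval of each list missed the true value, at -2.48 to -2.00 for the lowered and -0.21 to -0.01 for the unchanged list, the former ending just short of -2, so list values carry an error beyond their counting interval.

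The alternatives tried were no cell filter, a stricter filter (at least 500 genes and under 10% mitochondrial UMIs), leaving out cells marked by Scrublet, resolutions 0.5 and 2, a class per cell by marker score, clustering of both matrices together, CPM without hormone genes or without hormone, ribosomal and mitochondrial genes, TMM factors from edgeR 4.0.16 in R 4.3.3, a minimum of 50 UMIs, thinning of each cell to 500 UMIs, and hormone shares without ribosomal and mitochondrial genes. A further 3 were chosen after seeing the data: 10-week barcodes of 2000 UMIs or more only, leaving out hormone-rich cells, and random lists matched on exon length as well as abundance. Other tools were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9.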

Results

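The series concerns the anterior pituitary of mice fed a high fat diet, with oxidative stress and organelle pathology as its stated theme. Single-cell RNA sequencing was done on dissociated pituitaries of both sexes after 10 or 15 weeks on a diet with 60 kcal% fat or on a control diet with 10% fat, in thermoneutral housing. The labels describe 12 samples in 8 groups of sex, diet and week, with 1 sample per group at 10 weeks and 2 at 15 weeks. The analysed data were 2 matrices of deposited UMI counts, 1 for each time on the diet, over 31053 genes. The 10-week matrix held 2676 barcodes and 18695542 UMIs with a median of 4019 UMIs per barcode. The 15-week matrix held 875 barcodes and 1175786 UMIs with a median of 1093. All barcodes carried 1 suffix, and no map from cells to the labelled samples was used here. Each matrix was therefore treated as 1 sample. No comparison of diets or of sexes could be made and no difference has a replicate check. Every interval below is a 95% interval that covers counting error only. The cell filter left 2216 cells with 17550913 UMIs at 10 weeks and all 875 cells at 15 weeks.

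The first comparison asked which pituitary cell classes each matrix held. Lactotrope-like cells, the class of the prolactin-secreting cells, were the most numerous class in both matrices, at 38.1% of cells at 10 weeks (845 of 2216, exact binomial interval 36.1 to 40.2) and 66.7% at 15 weeks (584 of 875, 63.5 to 69.9). Stem cell-like cells, named from the Sox2 class of markers, made up 9.93% (220 cells, 8.71 to 11.2) and 12.1% (106 cells, 10.0 to 14.5). Somatotrope-like cells, the class of the growth hormone-secreting cells, made up 9.70% (215 cells, 8.50 to 11.0) and 10.4% (91 cells, 8.46 to 12.6). At 10 weeks 2 clusters with 15.3% of cells stayed unnamed (339 cells), and at 15 weeks none did. The UMI limit of the naming rule was relative to each matrix, and no 15-week cluster fell under it. Cluster 9 at 10 weeks (median 961 UMIs) stayed unnamed by it. Clusters 1, 2 and 6 at 15 weeks (162, 68 and 197 cells, medians 1440.5, 1012.5 and 880 UMIs) were named lactotrope-like. Like cluster 9, they had no lactotrope marker among their top 10 genes. Unnamed cells did form at 15 weeks under other settings, with 348 of 875 at clustering resolution 2, 259 of 875 at resolution 0.5, 167 of 601 under the stricter cell filter and 101 of 873 without the cells marked by Scrublet. The lactotrope-like cells of the 2 matrices differed in depth, with a median of 13208 UMIs per cell at 10 weeks and 1056 at 15 weeks.

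The class shares depended on how cells were grouped, so that no difference between the matrices is read from them. The lactotrope-like share at 15 weeks was 29.8% at clustering resolution 2, 27.9% with a class given to each cell by its own marker score and 43.1% under the stricter cell filter, the somatotrope-like share at 15 weeks was 6.17% with both matrices clustered together, the stem cell-like share at 15 weeks was 8.0% by marker score, and no somatotrope-like class formed at 10 weeks without a filter or under the stricter one, or at 15 weeks at resolution 0.5 or without the cells marked by Scrublet.

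**Figure D1:**
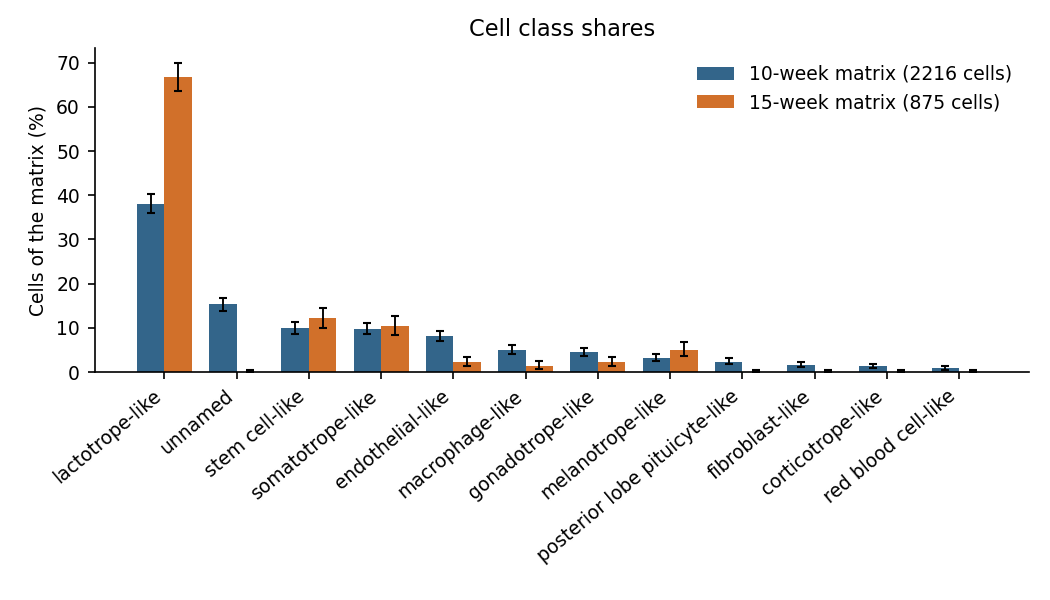
Share of cells (%) in each cell class, with 1 bar per matrix (10 weeks, 2216 cells; 15 weeks, 875 cells) and exact 95% binomial intervals for counting error only as error bars. Lactotrope-like cells are the largest class in both matrices (38.1% and 66.7%), and under this clustering the unnamed cells (15.3%) are from the 10-week matrix.

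The second comparison set the hormone genes of each class beside their level in classes that should not make the hormone. Prl, which encodes prolactin (chromosome 13, 27057570 to 27065205, 5 merged exons, GRCm38), took 45.5% of all UMIs of lactotrope-like cells at 10 weeks (45.4 to 45.5) and 13.5% at 15 weeks (13.4 to 13.5). Gh, which encodes growth hormone (chromosome 11, 106300271 to 106301865, 5 merged exons), took 21.1% of the UMIs of somatotrope-like cells at 10 weeks (21.0 to 21.2) and 4.29% at 15 weeks (4.19 to 4.39). The median somatotrope-like cell had 19.2% of its UMIs from Gh at 10 weeks and 0.438% at 15 weeks. At 10 weeks a Gh UMI was found in 97.7% of somatotrope-like and in 75.4% of lactotrope-like cells. At 15 weeks a Gh UMI was found in 79.1% of somatotrope-like cells (median 1553 UMIs per cell) and in 18.7% of lactotrope-like cells (median 1056).

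Hormone transcripts were also counted outside their own class. Prl took 1.55% of the UMIs of endothelial-like cells and 0.548% of those of macrophage-like cells at 10 weeks, and 2.00% and 0.204% at 15 weeks. At 10 weeks it took 13.4% in fibroblast-like cells (median cell 0.360%) and 9.77% in posterior lobe pituicyte-like cells (median cell 0.520%), and 30.4% in the 18 red blood cell-like cells (median cell 14.9%). In somatotrope-like cells Prl took 11.6% of UMIs at 10 weeks, where the median cell had 0.658%, and 5.05% at 15 weeks, where the median cell had 2.91%. In stem cell-like cells Prl took 9.36% of UMIs at 10 weeks (median cell 0.445%) and 2.67% at 15 weeks (median cell 0.298%). Gh took 4.30% of UMIs in stem cell-like cells at 10 weeks (median cell 0.0472%), and 0.0636% in lactotrope-like cells. Cells with over 5% of UMIs from hormone genes not of their class numbered 60 of 215 somatotrope-like and 72 of 220 stem cell-like cells at 10 weeks, and 35 of 91 and 27 of 106 at 15 weeks. Without them the Gh share of somatotrope-like cells was 30.2% at 10 weeks and 7.07% at 15 weeks, an alternative chosen after the data had been seen.

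The third comparison asked how stress, organelle and signalling genes differed between cell classes of 1 matrix. Each matrix was clustered alone. Values for gene lists are the median log2 CPM ratio of the list minus that of 10000 random lists matched on abundance, called the relative value, and values for single genes are the log2 CPM ratio minus the median over all genes considered. Stem cell-like cells had higher levels of the oxidative stress defence list than lactotrope-like cells in both matrices, with a relative value of 0.50 at 10 weeks (0.36 to 0.67, percentile 99.9 of the random lists) and 0.44 at 15 weeks (0.20 to 0.79, percentile 99.2). The unfolded protein response and ER chaperone list was lower in stem cell-like cells against matched lists, at -0.63 (-0.72 to -0.56) and -0.75 (-0.98 to -0.55), with percentile 0 in both. Its summed level differed less at 10 weeks, at 5434 against 5941 CPM (log2 ratio -0.13, -0.16 to -0.10), where 10 of 22 members had a higher CPM. At 15 weeks the sum was 5076 against 7686 CPM. Of the measured members, 19 of 25 oxidative stress defence genes at 10 weeks and 13 of 18 at 15 weeks lay above the median of the matched lists, against 1 of 22 and 2 of 20 chaperone genes.

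Among the oxidative stress defence genes, the metallothionein gene Mt1 stood at 4231 CPM in stem cell-like and 371 CPM in lactotrope-like cells at 10 weeks, which is 2.73 on the log2 scale relative to all genes (2.68 to 2.79). At 15 weeks it stood at 375 and 117 CPM (1.70, 1.22 to 2.18). Mt2 was at 3.86 at 10 weeks (3.71 to 4.01). Txnip, a member of the list although it encodes an inhibitor of thioredoxin, was at 3.19 at 10 weeks (3.04 to 3.34) and 4.11 at 15 weeks (3.52 to 4.74). Gstm1, a glutathione transferase gene of the list, was also among the leading genes of a stem cell-like cluster and is not read as a result. Among the chaperone genes, Hspa5, which encodes the ER chaperone BiP, was at -0.93 at 10 weeks (-1.0 to -0.85) and -0.89 at 15 weeks (-1.16 to -0.64), with 943 against 1047 CPM and 783 against 1476 CPM. Manf, which encodes an ER stress-induced secreted factor, was at -1.45 at 10 weeks (-1.54 to -1.35).

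The other lists of stem cell-like cells follow. The inflammation list had relative values of 2.96 (2.83 to 3.1) at 10 weeks and 2.44 (2.04 to 2.82) at 15 weeks. Its most abundant members were the MHC class I antigen presentation genes H2-D1, at 2.85 and 2.52, H2-K1, at 3.82 and 3.74, and B2m, at 2.54 and 3.21, rather than cytokine genes. The immediate early and heat shock list was at 1.26 (1.18 to 1.34) and 0.70 (0.35 to 0.89), with the transcription factor genes Jun at 1.80 and 2.31 and Egr1 at 1.45 and 1.15. The list of metabolic hormone receptors and signalling was at 1.07 (0.76 to 1.36) and 0.72 (0.24 to 1.29). In it, the summed level at 15 weeks was 3108 CPM against 3498 CPM in lactotrope-like cells (log2 ratio -0.17, -0.30 to -0.04). Socs3, a feedback inhibitor of cytokine signalling, was at 1.69 and 2.27, and Thrb, a thyroid hormone receptor gene, was at -1.36 at 15 weeks (-1.62 to -1.12). Lipid and cholesterol metabolism was at 0.89 and 0.59. Some lists lay within the range of the random lists. These were mitochondrially encoded genes at 0.43 and 0.005 (percentiles 92.9 and 54.1), nuclear oxidative phosphorylation at -0.04 and -0.22 (38.1 and 8.19), and mitophagy, lysosome and autophagy at 0.18 and 0.09 (87.4 and 64.1). The remaining lists were secretory granule and prohormone processing at -0.27 and -0.47, ribosomal proteins at -0.55 and -0.60, and nuclear-retained transcripts at 0.32 and 0.02 (percentiles 72.9 and 54.2).

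In somatotrope-like cells the oxidative stress defence list had a relative value of 0.06 (-0.06 to 0.18, percentile 70.1) at 10 weeks and -0.00 (-0.23 to 0.26, percentile 48.9) at 15 weeks, so that no difference was detectable against matched lists. Its summed level at 10 weeks was 6353 CPM against 3183 CPM in lactotrope-like cells, with a log2 ratio of 1.0 (0.97 to 1.03), and 18 of 23 members had a higher CPM. Within it, Mt1 was at 2.48 (2.41 to 2.54) and 0.88 (0.28 to 1.45) and Mt2 at 2.52 at 10 weeks (2.33 to 2.71). Gpx4, which encodes a phospholipid hydroperoxide glutathione peroxidase, was at -0.34 at 10 weeks (-0.47 to -0.22). The chaperone list was at -0.11 (-0.21 to -0.01, percentile 9.54) and -0.16 (-0.32 to 0.01, percentile 4.48). Nuclear oxidative phosphorylation was at -0.26 (-0.31 to -0.21, percentile 0) and -0.33 (-0.57 to -0.10, percentile 0.32). The list of metabolic hormone receptors and signalling was at 0.67 (0.31 to 1.11) and 0.57 (0.21 to 0.86), with Socs3 at 1.67 and 1.24 and the glucocorticoid receptor gene Nr3c1 at 4.89 at 10 weeks (4.30 to 5.54). Inflammation was at 0.82 and 0.46, and immediate early and heat shock genes were at 0.60 and 0.12. Lipid and cholesterol metabolism was at 0.52 and 0.05. The remaining lists were secretory granule and prohormone processing at 0.34 and 0.13, mitophagy, lysosome and autophagy at 0.16 and -0.10, mitochondrially encoded genes at -0.07 and -0.15, ribosomal proteins at -0.15 and -0.21, and nuclear-retained transcripts at 0.19 and 0.01.

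Of these values, the oxidative stress defence list of stem cell-like cells at 15 weeks rose to 0.85 under the stricter cell filter and 1.23 at resolution 2, and the chaperone list of stem cell-like cells moved to -0.98 at 10 weeks without hormone-rich cells and to -0.37 at 15 weeks with each cell thinned to 500 UMIs. In somatotrope-like cells the receptor list at 15 weeks turned to -0.23 under the stricter filter, and the chaperone list at 10 weeks moved to -0.25 without hormone-rich cells and -0.24 with 10-week barcodes of 2000 UMIs or more, while with thinning the oxidative stress defence list at 10 weeks was at -0.10 and mitochondrially encoded genes at 0.31. Their nuclear-retained transcripts at 10 weeks turned to -0.028 at resolution 0.5 and to -0.0093 with 10-week barcodes of 2000 UMIs or more.

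**Figure D2:**
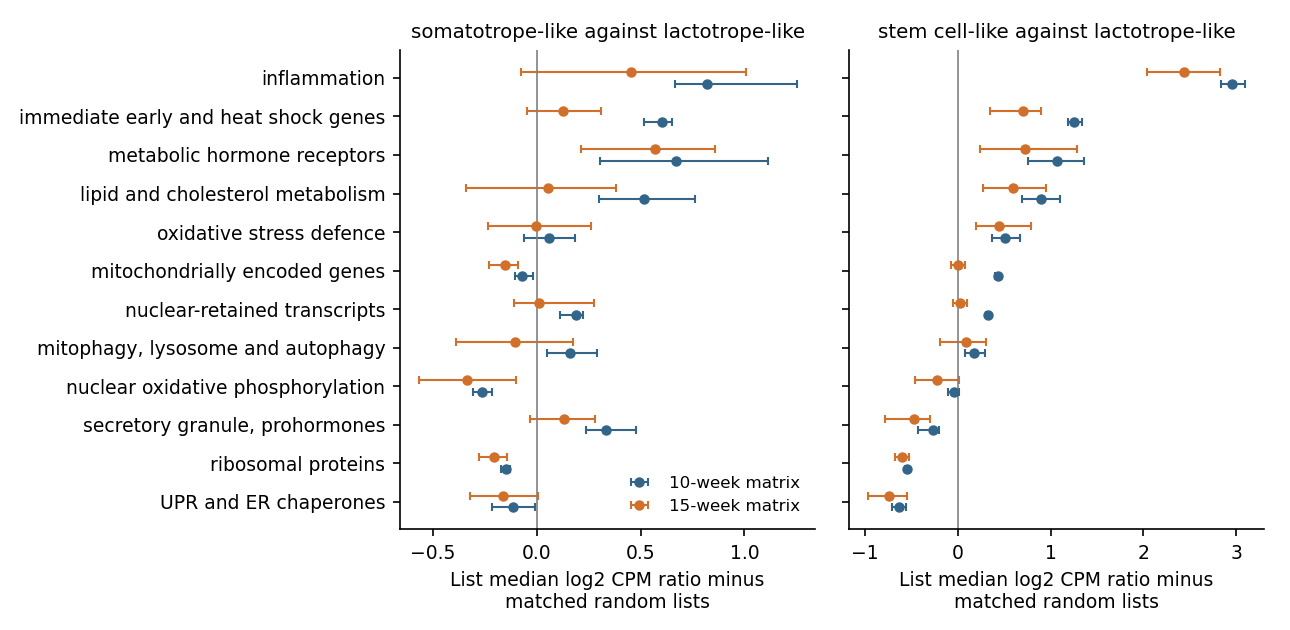
Relative value of each gene list (median log2 CPM ratio minus that of abundance-matched random lists) in somatotrope-like (left) and stem cell-like (right) cells against lactotrope-like cells of the same matrix, with 95% intervals for counting error only and 1 colour per matrix. In stem cell-like cells the oxidative stress defence list lies above 0 (0.50 and 0.44) and the chaperone list below 0 (-0.63 and -0.75) in both matrices.

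The fourth comparison set the 15-week matrix against the 10-week matrix within the 3 classes with at least 50 cells in each. The somatotrope-like class differed in hormone content. At 10 weeks Gh took 21.1% and Prl 11.6% of its UMIs (median cell 19.2% and 0.658%). At 15 weeks Gh took 4.29% and Prl 5.05% (median cell 0.438% and 2.91%). A different make-up of this class can therefore not be told apart from a difference between weeks. The same holds for the other classes, where hormone shares differed too. At 10 and 15 weeks Prl took 45.5% and 13.5% of UMIs in lactotrope-like cells and 9.36% and 2.67% in stem cell-like cells. Transcripts of the nuclear-encoded oxidative phosphorylation subunits were lower at 15 weeks in all 3 classes, with relative values of -3.54 in lactotrope-like (-3.77 to -3.31), -3.40 in somatotrope-like (-3.73 to -3.07) and -3.17 in stem cell-like cells (-3.51 to -2.89), each at percentile 0. Their summed level was 9249 CPM at 10 weeks and 2360 CPM at 15 weeks in lactotrope-like cells, 8658 and 1880 CPM in somatotrope-like cells, and 11852 and 2067 CPM in stem cell-like cells. In lactotrope-like cells Cox8a, a cytochrome c oxidase subunit gene, was at -3.47 relative to all genes (-3.82 to -3.15) and Atp5g1, an ATP synthase subunit gene, at -3.05 (-3.35 to -2.76). Cox8a was at -2.97 (-3.75 to -2.28) in somatotrope-like and -3.09 (-3.80 to -2.46) in stem cell-like cells. Ribosomal protein transcripts were lower to a like extent, at -3.09, -3.52 and -3.15 in the same order.

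The oxidative stress defence list was also lower at 15 weeks, at -1.55 in lactotrope-like (-1.81 to -1.24, percentile 0.02), -1.81 in somatotrope-like (-2.27 to -1.39, percentile 0.01) and -1.22 in stem cell-like cells (-1.59 to -0.69, percentile 0.79). This depended on the setting: with each cell thinned to 500 UMIs the value was 0.43 in somatotrope-like cells (-0.26 to 1.0), and against random lists also matched on exon length the values were -0.51, -0.92 and -0.23 (percentiles 4.70, 0.31 and 27.4). Its members moved apart. Sod1, which encodes the cytosolic superoxide dismutase, was higher, at 3.56 (3.42 to 3.69), 3.81 (3.50 to 4.13) and 3.87 (3.62 to 4.12), with 1327 against 70.1 CPM in lactotrope-like cells. Whether both matrices share chemistry and reference is not given in the sources used here, and other abundant transcripts differed too, with Actb at 0.128% of kept UMIs at 10 weeks and 2.26% at 15 weeks and Gm42418 at 0.239% and 4.37%. Sod2 of the mitochondrial matrix was at 0.70 in lactotrope-like and 0.78 in somatotrope-like cells. Mt1 was lower, at -3.86 in somatotrope-like (-4.37 to -3.39) and -3.44 in stem cell-like cells (-3.81 to -3.10), and Gpx4 was at -1.64 in lactotrope-like cells (-1.91 to -1.39). The sum of the list was 3183 CPM at 10 weeks and 3281 CPM at 15 weeks in lactotrope-like cells, 6338 and 3551 CPM in somatotrope-like cells, and 11578 and 5688 CPM in stem cell-like cells. With hormone genes left out of the total, the level in lactotrope-like cells was 5857 and 3826 CPM. The mitophagy, lysosome and autophagy list was at -1.15 (percentile 1.28), -1.73 (percentile 0.01) and -0.97 (percentile 2.32). Among its members were the autophagosome gene Gabarap at -1.92, -1.04 and -1.21 and the lysosomal membrane gene Lamp2 at 1.42 in somatotrope-like and 1.37 in stem cell-like cells.

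Lists of other organelles and pathways lay within the range of matched random lists. The chaperone list was at -0.67 (percentile 11.0), -0.79 (percentile 5.52) and -0.77 (percentile 5.39). Among its members were Canx, which encodes the chaperone calnexin, at 2.60, 2.70 and 2.65 and Manf at -2.37 in lactotrope-like cells. Secretory granule and prohormone processing was at -0.37, -0.24 and -0.59, but at 0.04 in lactotrope-like and 0.26 in somatotrope-like cells with CPM taken without hormone, ribosomal and mitochondrial genes, at 0.21 in somatotrope-like cells with TMM factors, and at 0.44 in stem cell-like cells without hormone-rich cells. Among its members were Pam, which encodes the enzyme that amidates peptide hormones, at 4.41, 4.74 and 4.99, and Scg5 at -1.43 in lactotrope-like cells. Lipid and cholesterol metabolism was at 0.37, 0.25 and 0.25. The summed level of this list had log2 ratios of 2.10 (1.99 to 2.21), 1.47 (1.26 to 1.67) and 0.19 (0.02 to 0.35). In lactotrope-like cells it was 283 CPM at 10 weeks and 1212 CPM at 15 weeks. Members of the list included Insig1, which retains sterol regulators in the ER, at 3.32, 3.80 and 4.04. The receptor list was at 0.78, 0.65 and 0.16. Log2 ratios of its summed level were 2.30 (2.24 to 2.37), 1.04 (0.91 to 1.17) and 0.42 (0.30 to 0.55). In lactotrope-like cells the sum was 715 CPM at 10 weeks and 3528 CPM at 15 weeks. Members of the receptor list included Thrb at 3.56, 4.17 and 3.35 and Igf1r at 1.57, 1.68 and 1.20, while Socs3 was at -1.15, -1.48 and -0.62. Mitochondrially encoded genes were at 0.63, 0.79 and 0.44, and inflammation was at -0.56, -0.83 and -1.0. Immediate early and heat shock genes were at -0.44, -0.70 and -0.01. The -0.44 became 0.05 with CPM taken without hormone, ribosomal and mitochondrial genes and 0.07 with TMM factors. Nuclear-retained transcripts were at 0.49, 1.35 and 1.77. All these values are for lactotrope-like, somatotrope-like and stem cell-like cells in this order, and each list of this paragraph lay between percentiles 5 and 95. H2-K1 in stem cell-like cells was at -1.95 (-2.37 to -1.56), and Neat1 was at 2.79, 2.77 and 3.00.

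There was 1 matrix per time, and which labelled samples each matrix holds is not known. Time on the diet, preparation, sequencing and the make-up of each matrix by sex and diet can therefore not be told apart. Short transcripts were lower at 15 weeks as a whole. The median log2 CPM ratio in lactotrope-like cells was -1.29 for genes of up to 1000 exonic bases and 1.49 for genes of over 8000. Against random lists also matched on exon length the oxidative phosphorylation list was at -1.52, -1.51 and -1.28. The mitophagy list was then at -0.53, -1.13 and -0.38 (percentiles 10.6, 0.505 and 12.9), and mitochondrially encoded genes were above the range of the random lists, at 2.27, 2.19 and 1.97. With this matching nuclear-retained transcripts turned to -1.32, -0.96 and -0.82 and the receptor list of somatotrope-like cells to -0.02, and with each cell thinned to 500 UMIs the oxidative phosphorylation list was at -3.32 in lactotrope-like, -1.47 in somatotrope-like and -1.97 in stem cell-like cells.

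**Figure D3:**
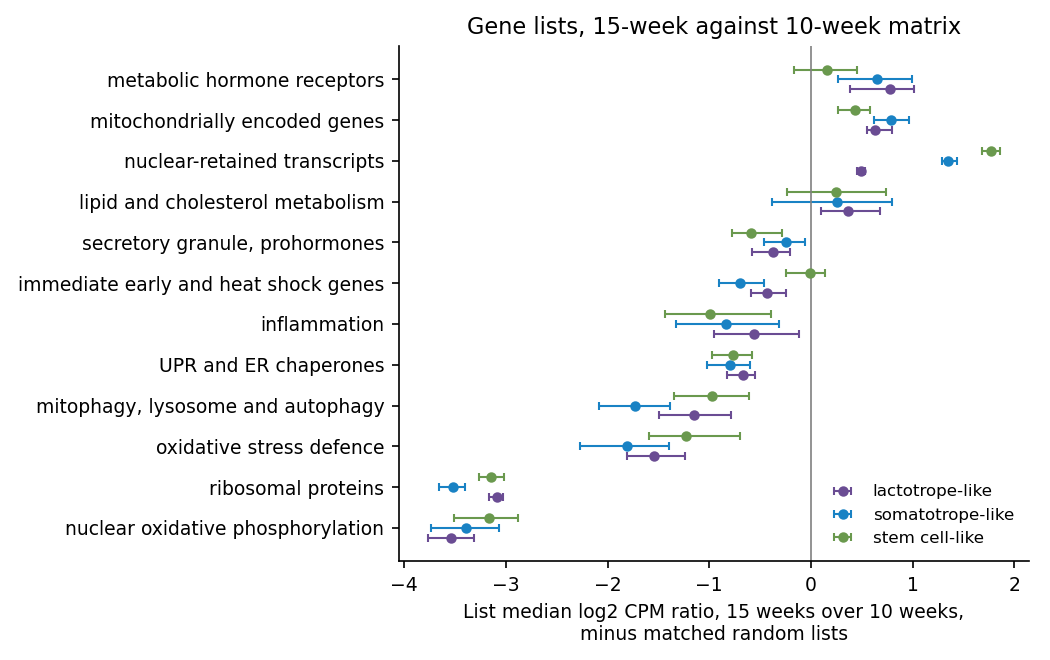
Relative value of each gene list (median log2 CPM ratio, 15 weeks over 10 weeks, minus that of abundance-matched random lists) in lactotrope-like, somatotrope-like and stem cell-like cells, with 95% intervals for counting error only. The nuclear oxidative phosphorylation (-3.54, -3.40 and -3.17) and ribosomal protein lists (-3.09, -3.52 and -3.15) lie farthest below 0, each matrix being 1 sample.

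The genes named by the size rule as higher at 15 weeks were largely scarce or unnamed transcripts. In lactotrope-like cells these were Gm17275, Gm26879, Chdh (choline dehydrogenase), Ccdc152, Olfr77, Gm26526, Gm26825, Tmem255a, Shc4 (a signalling adaptor) and Nphs1 (nephrin), each with 0 to 18 UMIs at 10 weeks. Gm26825 had 304 UMIs at 15 weeks and 18 at 10 weeks, a value of 7.37 relative to all genes (6.69 to 8.14). Ccdc152 had 83 UMIs at 15 weeks and none at 10 weeks. It was at least 347-fold higher on the CPM scale by the lower interval end, and 436-fold higher against a floor of 3 counts at 10 weeks. In somatotrope-like cells the genes were Gm26526, Ccdc152, Gm17275, Shc4, Gm26733, Notch2, Gm26825, Gm7292, Gm11175 and Scn2b, a sodium channel subunit gene that stood at 6.43 (5.58 to 7.42). In stem cell-like cells they were Ccdc152, Gm26825, Gm17275, Thbd (thrombomodulin), Gm11175, Tbx3os1, Gm26526, Gm26879, Fn3krp and Gm20721, the last at 6.28 (5.47 to 7.20). Notch2 and Tbx3os1 had no UMI at 10 weeks in these classes. They were at least 98.8-fold and at least 104-fold higher by the lower interval end (127-fold and 133-fold against the same floor).

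In lactotrope-like cells the genes named as lower at 15 weeks were Supt4a, Bola1, Park7, Ethe1, Krt10, Vamp8, Znhit3, Crb3, Gm2000 and Mrps18c. The redox sensor gene Park7 was at -4.59 (-5.55 to -3.79) from 2837 UMIs at 10 weeks and 12 at 15 weeks. In somatotrope-like cells they were 1810037I17Rik, Ndufa13, Uqcrq, Tmsb4x, Psmb6, Glrx5, Dpm3, Ndufa8, Uqcrh and Pfdn5, of which Ndufa13, Ndufa8, Uqcrq and Uqcrh encode respiratory chain subunits. Uqcrh was at -4.63 (-6.51 to -3.27). In stem cell-like cells they were Dbi, Ttr, Snrpd2, Ndufb7, Psmb6, Snrpe, Dpm3, Rex1bd, Park7 and Mrpl14. Dbi, which encodes the acyl-CoA-binding protein, was at -5.82 (-8.10 to -4.27) and Park7 at -4.54 (-6.82 to -2.99). Ttr (transthyretin) had 1236 UMIs at 10 weeks and none at 15 weeks. At 15 weeks the genes named as lower had 1 to 12 UMIs in lactotrope-like, 1 to 6 in somatotrope-like and 0 to 3 in stem cell-like cells. Their ratios therefore rest on few counts. A gene with 0 UMIs was set to the floor of 3 counts, so it could rank behind a gene with 1 UMI. The order by ratio is thus uncertain.

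The values of several of the genes named as higher are uncertain, because their exons overlap those of a gene on the other strand and the strand use of the counting is not given in the sources used here. This held for 7 of the 10 genes in lactotrope-like, 6 in somatotrope-like and 6 in stem cell-like cells, among them Gm17275 opposite H3f3a, Ccdc152 opposite Selenop, Gm11175 opposite Jund and Gm20721 opposite Gnas, and for 4, 1 and 1 of the genes named as lower.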

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

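Of the tests in this part, the one on time on the diet was planned before the result was seen, and all the others were chosen only after it was seen, although thinning had been listed before as an alternative.

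Signals appeared in 10-week barcodes that belonged to no named class under the main settings. The 460 barcodes left out by the cell filter held 92.3% of their UMIs in hemoglobin transcripts and Alas2, a heme synthesis gene, and 409 of them had most of their UMIs from these genes. The unnamed cluster 9 (209 cells, median 961 UMIs) had 42.5% of its UMIs from Prl, close to the 45.5% of lactotrope-like cells, with 4.46% from Malat1 and 1.39% from Meg3, which encode nuclear transcripts. The unnamed cluster 13 (130 cells, median 991 UMIs) had 29.5% from Prl, 16.8% from Gh and 3.02% from Pomc, the transcripts of hormones from 3 different cell classes. No explanation of these clusters was tested.

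The lower nuclear oxidative phosphorylation transcripts at 15 weeks were weighed first. Exon length, taken over all annotated exons of a gene merged, is argued against as the whole cause. Against random lists matched on it the list stayed at -1.52 in lactotrope-like, -1.51 in somatotrope-like and -1.28 in stem cell-like cells. The upper interval ends were -1.29, -1.18 and -1.0. Length could still account for a part, because the values without this matching were -3.54, -3.40 and -3.17. Merged exons can be longer than the transcripts a gene makes, so transcript length itself was not tested and stays open. UMIs per cell as the whole cause are argued against too, since with each cell thinned to 500 UMIs the list was at -3.32 in lactotrope-like (-3.58 to -3.03), -1.47 in somatotrope-like (-2.12 to -0.95, 16 members measured) and -1.97 in stem cell-like cells (-2.44 to -1.52), but depth could account for a part in the last 2 classes. Time on the diet stays open as an untested biological explanation. With 1 matrix per time on the diet, it cannot be told apart from preparation, sequencing or the unknown make-up of each matrix by sex and diet. Nor can time on the diet be told apart from a different make-up of the cell classes, since hormone shares differed between weeks in each of them. Ribosomal protein transcripts also stayed lower with length matching, at -1.71, -1.68 and -1.75.

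The genes named as higher at 15 weeks that lie opposite another gene were weighed next. UMIs taken from the opposite strand throughout the 15-week matrix might raise scarce genes that overlap abundant ones. As a set, genes opposite a gene of at least 10 times their mean CPM lay against matched lists at -0.10 in lactotrope-like (106 genes, percentile 23.1), -0.081 in somatotrope-like (34 genes, percentile 26.0) and -0.033 in stem cell-like cells (52 genes, percentile 40.7), with upper interval ends of 0.12, 0.43 and 0.38. This test cannot decide, because a rise at 15 weeks raises the mean CPM and so takes a gene out of the set, and the set held 0 of 7, 1 of 6 and 3 of 6 of the named genes that lie opposite another gene. The form of this test was settled after an earlier look that chose genes by their 10-week CPM alone and seemed positive. The explanation stays open, and no biological explanation was tested.

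The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 UMIs in both matrices, although the labels name both sexes. A Y chromosome left out of the counting as a whole is argued against. Genes annotated on it had 2589 UMIs at 10 weeks and 190 at 15 weeks. All were of 1 gene, Gm47283 (chromosome Y, 90784738 to 90816464), and the other 732 had none. UMIs of this 1 gene do not show whether the Y-linked genes named above were counted or whether male cells were present. A partial loss stays open. At 10 weeks male cells at 50% or more of the matrix are argued against by Xist, as far as stray Xist came from free RNA. Xist is expressed from the inactive X chromosome of females and had a UMI in 82.1% of the 2216 kept cells. Male cells could make up 50% only if at least 64.2% (60.8 to 67.3) of the male cells held a stray Xist UMI. Barcodes with most UMIs from hemoglobin transcripts and Alas2, taken to make no Xist themselves, had one in 3.35% (1.84 to 5.56, 14 of 418). These barcodes had a median of 86 UMIs from other genes, against 6193.5 UMIs in kept cells. Stray Xist from sources other than free RNA was not measured. A smaller share of male cells stays open. At 15 weeks Xist could not decide on male cells at 50% or more. An Xist UMI was in 54.3% of 875 cells, and there were no such barcodes to measure free RNA. The X-linked counterparts Ddx3x, Eif2s3x, Kdm5c and Kdm6a had 290, 71, 386 and 239 UMIs at 15 weeks and 1940, 644, 559 and 474 at 10 weeks. Beside these, the 0 UMIs of the Y-linked genes argue against a large share of male cells only if those genes were counted. That was not tested. Which labelled samples the matrices hold stays open. An earlier form of this test, set aside because it left the shallower cells untested, found an Xist UMI in 98.6% of 869 cells with at least 10000 UMIs at 10 weeks and in 78.7% of 141 cells with at least 2000 UMIs at 15 weeks.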

How the results depend on the processing

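The alternatives with 10-week barcodes of 2000 UMIs or more, without hormone-rich cells and with lists matched on exon length were chosen after seeing the data, and so were the matched-list measure, the naming base and the single-gene value relative to all genes. No paired analysis was possible because the replicate numbers 1 and 2 in the 15-week labels are shared by all groups and no map ties cells to samples. Not run were equal weights per barcode suffix and leaving out each suffix, since there was 1 suffix, and every diet alternative (DESeq2, no count filter, a replicate block, leaving out each replicate), since no diet test was made. Where a value changed, the cause was not tested, unless stated.

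Among the main values of each comparison, 100 of those under alternatives chosen before the data were examined stayed within their interval, 51 moved beyond it and 1 reversed, which here means a change of sign from an interval that excluded 0. Under the later ones 32 stayed and 16 moved. For the other lists these numbers were 336, 117 and 9, and 107, 55 and 8 under the later ones. For single genes between weeks they were 819, 175 and 7, and 318, 52 and 4. For single genes between classes they were 315, 80 and 5, and 100, 59 and 1. Single genes under the scalings (CPM without hormone genes or without hormone, ribosomal and mitochondrial genes, and TMM) are not counted. By construction, a scaling cannot change the value relative to all genes. Other values that could not change are counted as staying within their interval. Without a filter, values from the 15-week matrix alone could not change, because all of its 875 barcodes had passed the filter. They could not change either under the later limit on UMIs per barcode, which was applied to the other matrix only. The numbers that stayed are therefore not all tests of the values. Lower oxidative phosphorylation transcripts at 15 weeks kept their direction under every alternative that gave a value.

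No somatotrope-like class formed at 10 weeks without a filter and under the stricter filter, or at 15 weeks at resolution 0.5 and without the cells marked by Scrublet, so these give no value for it. Without a filter at 10 weeks, lactotrope-like cells were 33.9% and stem cell-like cells 7.29%, and Prl was 45.3%. Under the stricter filter lactotrope-like cells were 49.1% and 43.1% (10 and 15 weeks, in this order throughout), Prl 47.4% and 12.0%, and Gh 6.26% at 15 weeks. There, oxidative stress defence in stem cell-like cells was 0.85 at 15 weeks, the somatotrope-like receptor list -0.23, oxidative phosphorylation in lactotrope-like cells -3.96 between weeks, B2m 0.012 in stem cell-like cells between weeks and Hsp90b1 0.026 in somatotrope-like against lactotrope-like cells at 15 weeks. Without cells marked by Scrublet, lactotrope-like cells were 40.3% and stem cell-like cells 8.61% at 10 weeks, Gh 24.4% at 10 weeks, and Prl 45.4% and 13.2%.

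At resolution 0.5, lactotrope-like cells were 48.3% and 56.7%, Prl 45.3% and 13.8%, Gh 21.6% at 10 weeks, oxidative phosphorylation in lactotrope-like cells -3.31, and nuclear-retained transcripts in somatotrope-like cells -0.028 at 10 weeks. At resolution 2, lactotrope-like cells were 29.8% and stem cell-like cells 9.94% at 15 weeks, somatotrope-like cells 7.94% and 7.89%, Prl 45.4% and 12.8%, Gh 26.3% and 5.32%, oxidative stress defence in stem cell-like cells 1.23 at 15 weeks and oxidative phosphorylation in somatotrope-like cells -2.93. With a class per cell, lactotrope-like cells were 33.7% and 27.9% and stem cell-like cells 8.44% and 8.0%. With both matrices clustered together, lactotrope-like cells were 48.8% and 72.2% and somatotrope-like cells 8.21% and 6.17%. Without mitochondrial and ribosomal genes, which shrinks the total, Prl was 52.9% and 14.5% and Gh 24.8% and 4.61%.

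With 10-week barcodes of 2000 UMIs or more, lactotrope-like cells were 50.5% and somatotrope-like cells 6.71% at 10 weeks, Prl 48.3% and Gh 24.7%. In somatotrope-like against lactotrope-like cells at 10 weeks, chaperones were -0.24, nuclear-retained transcripts -0.0093 and Fos 0.067, and between weeks secretory granule genes in somatotrope-like cells were 0.029. Without hormone-rich cells, Gh was 30.2% and 7.07%, chaperones at 10 weeks -0.25 in somatotrope-like and -0.98 in stem cell-like cells, and oxidative phosphorylation in somatotrope-like cells -3.02. Between weeks in stem cell-like cells, secretory granule genes were then 0.44, Chgb 1.32, Nnat 0.42, Pcsk1n 0.37 and Hsp90b1 0.065.

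With CPM taken without hormone, ribosomal and mitochondrial genes, the values between weeks were -3.14 for oxidative phosphorylation, 0.046 for immediate early and 0.037 for secretory granule genes in lactotrope-like cells, and 0.26 for secretory granule genes in somatotrope-like cells. With TMM factors the first was -3.16, the second 0.065 and the last 0.21. With lists matched on exon length, oxidative phosphorylation was -1.52, -1.51 and -1.28, oxidative stress defence -0.51, -0.92 and -0.23, and nuclear-retained transcripts -1.32, -0.96 and -0.82 (lactotrope-like, somatotrope-like, stem cell-like), while secretory granule genes were 0.026 in lactotrope-like and receptors -0.021 in somatotrope-like cells.

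With each cell thinned to 500 UMIs, between weeks oxidative phosphorylation stayed at -3.32 in lactotrope-like cells and was -1.47 in somatotrope-like and -1.97 in stem cell-like cells, oxidative stress defence -2.05 in lactotrope-like and 0.43 in somatotrope-like cells, and receptors -0.11 in somatotrope-like cells. Thinning leaves fewer UMIs, so fewer genes reach the minimum. Single genes that reversed between weeks were Btg2 (0.42, somatotrope-like), Meg3 (-0.082, lactotrope-like) and, in stem cell-like cells, Chgb (0.55), Hsp90b1 (0.26), Nnat (0.16) and Pcsk1n (0.82). At 10 weeks against lactotrope-like cells, somatotrope-like cells had Fos at 0.20, Hsp90b1 at 0.14, Pdia3 at 0.38, mitochondrially encoded genes at 0.31 and oxidative stress defence at -0.10, and stem cell-like cells had Igf1r at 0.43 and chaperones at -0.87, with chaperones at -0.37 at 15 weeks.

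The choice to name single genes between classes from 5 lists was made after reversals had been seen. Over these lists 6 of 560 values reversed, against 31 of 1204 over all lists, again without the scalings. Both totals include the values at 15 weeks that could not change. Relative to all genes, 20 of 172 genes between classes reversed with thinning. On the plain CPM ratio, the measure chosen at first, 16 of 172 genes between classes reversed with CPM without hormone genes and 8 with thinning, and between weeks 12 of 189 reversed without hormone, ribosomal and mitochondrial genes and 10 with TMM factors. Lactotrope-like cells at 15 weeks had a median of 1056 UMIs.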

Other observations

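Other cell classes showed their own hormone genes and list levels, given as values. In gonadotrope-like cells Cga, which encodes the shared alpha subunit of glycoprotein hormones, took 10.5% of UMIs at 10 weeks (101 cells) and 3.52% at 15 weeks (19 cells), and Lhb, the beta subunit gene of luteinizing hormone, 0.802% and 0.188%. In melanotrope-like cells Pomc, which encodes the precursor of melanocyte-stimulating hormone, took 16.9% (70 cells) and 2.48% (44 cells), and in corticotrope-like cells 5.81% at 10 weeks (28 cells). No cluster was thyrotrope-like in either matrix.

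At 10 weeks, lists were also compared between further classes and lactotrope-like cells. The inflammation list had relative values of 5.53 in endothelial-like and 6.0 in macrophage-like cells, where secretory granule genes were at -2.92 and -5.31. Gonadotrope-like cells had mitochondrially encoded genes at 0.99. Oxidative stress defence was at 0.37 in gonadotrope-like, 0.43 in posterior lobe pituicyte-like, -0.66 in macrophage-like (percentile 2.03), -0.46 in endothelial-like (percentile 6.57) and -0.39 in melanotrope-like cells (percentile 2.21). The chaperone list was at -0.82 in endothelial-like, -1.0 in macrophage-like, -0.47 in gonadotrope-like, -0.66 in melanotrope-like and -0.52 in posterior lobe pituicyte-like cells. Posterior lobe pituicyte-like cells had mitochondrially encoded genes at 0.68 and secretory granule genes at -1.45. These values were computed under 1 setting only.

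Among the sex-linked transcripts, Xist had a UMI in 82.1% of all kept cells at 10 weeks and 54.3% at 15 weeks, with medians of 6193.5 and 1093 UMIs per cell. Some abundant transcripts differed between the matrices as a whole: Gm42418, which overlaps ribosomal RNA, took 0.239% of kept UMIs at 10 weeks and 4.37% at 15 weeks, AY036118 0.0172% and 0.90%, and the actin gene Actb 0.128% and 2.26%.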
